A study of Homo sapiens with 36 samples.

How the data were processed

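RNA was measured by sequencing in 36 libraries of HEK293T cells, 3 in each of 12 groups: input, YTHDF1 RIP, YTHDF2 RIP and YTHDF3 RIP from lines that expressed YTHDF1-ADAR, YTHDF2-ADAR or YTHDF3-ADAR. Per the labels, the fusions were induced with doxycycline at 1 ug/mL for 24 h, lysates went through RIP with antibodies to the endogenous proteins, a fraction of lysate was kept as input, and libraries were made with DNase treatment, rRNA depletion and a directional kit. Grouping followed the labels. The replicates are not stated to be separate cultures, so p-values measure the spread between these samples.

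Per the submitters' processing notes, the authors aligned reads to GRCh38/hg38 with STAR 2.7.7, counted them with featureCounts 2.0.1 and compared groups with DESeq2. The deposited gene table of each library holds read counts. Per the file headers, these counts include reads that map to several places or overlap several genes, ignore marked duplicates, and were made without strand, so genes with copies, paralogs, overlapping or antisense partners share counts and are reported as uncertain where named. A rat Apobec1 sequence was part of the authors' annotation. The authors' deposited DESeq2 table gives a mean signal (its baseMean column), a log2 fold change and a p-value per gene; it was used for symbols and for a comparison of fold changes. In the authors' deposited editing tables each gene has a number of sites, a score, a natural log odds ratio and a p-value. From the values, the score acts as the number of sites times an editing fraction, and the natural log odds ratio is that of this fraction between RIP and input (matched within 1e-06 for genes with a value in every arm; genes missing an arm often did not match and were left out of the levels). The editing level used here is 100 times the score divided by the number of sites, a percent. Replicates are pooled in the authors' deposited editing tables, so editing is described per gene with the authors' values and no test of its own; the unit differed from the first choice of the design, which was sites. The tables hold 60675 genes; symbols came from the authors' deposited table for 40818 and from a reference table for 1276, and 18581 genes had none. No column of the count tables was left out (0 not used).

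Counts per library ran from 12.5 to 37.5 M (mean 26.4, SD 6.93, median 28.1): inputs 20.7 to 35.3, YTHDF2 RIP 15.9 to 30.8, YTHDF3 RIP 26.3 to 37.5, and YTHDF1 RIP 22.7 to 33.5 in YTHDF1-ADAR cells and 12.5 to 16.3 in the other lines. Precision is given as the standard error of each log2 fold change, or as SD over 3 libraries.

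Genes with enough counts in the smallest group (edgeR filterByExpr) were tested, 31849 of 60675; 28826 were not. Libraries were scaled by TMM. One model with the 12 groups was fitted by edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust = TRUE, glmQLFTest), and p-values were adjusted over genes by Benjamini-Hochberg with a limit of 0.05. Each RIP was set against input, and RIPs against one another, as averages over the 3 lines; inputs were compared between lines; and the difference in RIP enrichment between lines was tested as an interaction. Results per line and the difference of 1 line against the mean of the others came from the same model. TMM assumes that most genes do not differ between arms, which a RIP can break, so results under other scalings are given beside those by TMM.

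Genes named in the text followed a rule fixed before the data were examined, as were the comparisons, the lists and most alternatives. For each RIP against input these were the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, mean log2 CPM of at least 4 and the same sign in each line. RIP against RIP used the 5 highest and 5 lowest under the same conditions, inputs the 5 highest and 5 lowest, and interactions the 5 smallest p. For each list 2 to 4 genes of smallest p were named, and YTHDF1, YTHDF2, YTHDF3, ADAR, ADARB1, METTL3, METTL14, SON, CREBBP, ACTB, MYC, GAPDH, HPRT1, RPL30 and MALAT1 were always read. A gene that met the rule for inputs is not reported.

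Gene lists numbered 26: cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, proteasome subunits, translation initiation factors, replication-dependent histones, ZNF zinc finger genes, small structured noncoding RNAs, snoRNA host genes, olfactory receptor genes (as a check on genomic DNA), nuclear long noncoding RNAs, m6A writers, erasers and readers, mRNAs widely described as m6A-modified, mRNAs used as low-m6A controls, immediate-early genes, chromatin and transcription coregulators, CCR4-NOT and P-body components, stress granule components, secretory pathway and cell surface proteins, interferon-stimulated genes, G2/M genes, S phase genes, and markers of blood, fibroblast, and epithelial and hepatocyte cells. They were tested with camera (limma 3.58.1, voom values, inter-gene correlation of 0.01), adjusted over the 26 lists, and again with a correlation estimated per list and with fry.

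Alternatives were DESeq2 1.42.0, its size factors within edgeR, total counts, scaling to mitochondrial mRNAs, no expression filter, a mean of at least 100 counts, glmTreat at 1.5-fold, each line alone, only the libraries of the arms compared, only the 9 inputs, each library left out, and a block for replicate number. Settings added after the data were seen left out the libraries with an unusual profile, kept protein-coding genes only, or used YTHDF1 RIP of YTHDF1-ADAR cells only for shared genes. Principal components used log2 CPM with a prior count of 2. The model was tested on simulated data with 28404 genes for each comparison. For YTHDF2 RIP against input it called 30 of 67 genes changed 1.5-fold, 50 of 67 changed 2-fold and 62 of 66 changed 4-fold, with 11 false calls of 218. It called fewer for inputs (7, 9 and 1 of 67 at 1.5-fold in the 3 comparisons) and for the interactions (4, 0 and 0 of 67 at 1.5-fold and 14, 16 and 13 of 67 at 2-fold for YTHDF1, YTHDF2 and YTHDF3 RIP). Figures were made with matplotlib 3.10.9 in Python 3.11.15.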

Results

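RNA sequencing counts were analysed from HEK293T cells, a human embryonic kidney line, that expressed YTHDF1, YTHDF2 or YTHDF3 fused to ADAR. YTHDF proteins read N6-methyladenosine (m6A) in mRNA, and ADAR turns adenosine into inosine, so that a fusion leaves edited sites on the RNAs it meets (TRIBE). From each of the 3 lines, RNA came from input lysate and from RNA immunoprecipitation (RIP) with an antibody to endogenous YTHDF1, YTHDF2 or YTHDF3. This gave 12 groups of 3 libraries, 36 in all. Counts per library averaged 26.4 M (SD 6.93, range 12.5 to 37.5). Fold changes below are log2 values ± standard error, relative to the other RNAs of a library after TMM scaling. Genes called higher or lower passed 0.05 on the Benjamini-Hochberg-adjusted p of edgeR's quasi-likelihood test.

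The fusion genes were read first, to see which line carried which fusion. YTHDF1, YTHDF2 and YTHDF3 are close relatives that the fusions add to, and ADARB1, the gene of the ADAR family member ADAR2, is normally most active in brain. In the 9 inputs, YTHDF1 (ENSG00000149658, GRCh38 chr 20 63195429 to 63216139) lay at 634 ± 97.4 CPM (TMM-scaled counts relative to library size; mean ± SD, n = 3) in YTHDF1-ADAR cells, against 87.9 ± 2.03 in YTHDF2-ADAR and 94.0 ± 5.10 in YTHDF3-ADAR cells. YTHDF2 (ENSG00000198492, chr 1 28736621 to 28769775) lay at 154 ± 22.7, 321 ± 2.26 and 197 ± 6.78 CPM in the same order, and YTHDF3 (ENSG00000185728, chr 8 63168553 to 63212786) at 52.8 ± 5.99, 54.8 ± 8.83 and 122.6 ± 14.6. ADARB1 (ENSG00000197381, chr 21 45073853 to 45226560) lay at 521 ± 40.0, 58.2 ± 1.998 and 2091 ± 56.6 CPM. Each YTHDF gene was thus highest in the line named for it, while ADARB1 differed between lines far more than the YTHDF genes did. ADARB1 was lowest in YTHDF2-ADAR cells, so its counts do not show the ADAR part of that fusion. The single libraries of the YTHDF1-ADAR line held YTHDF1 at 529, 721 and 652 CPM and ADARB1 at 474, 546 and 542.

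**Figure D1:**
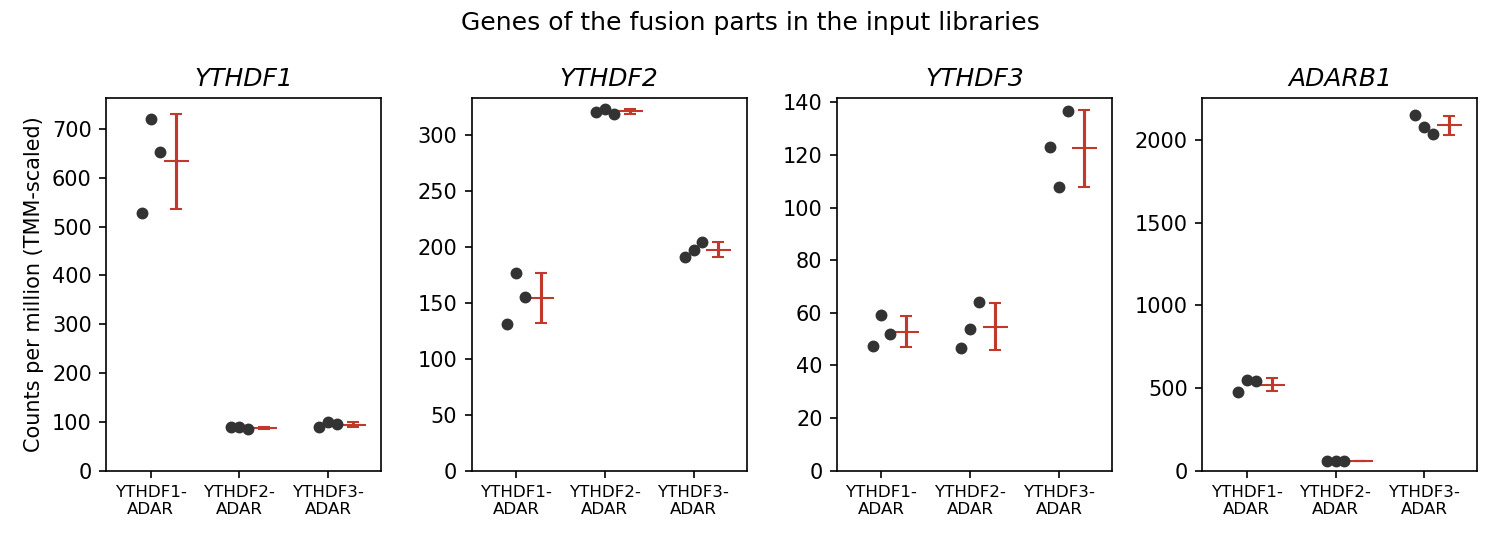
TMM-scaled CPM of YTHDF1, YTHDF2, YTHDF3 and ADARB1 in the 9 input libraries by cell line; each point is a library and the bars give mean ± SD (n = 3). YTHDF1 reached 634 CPM in YTHDF1-ADAR cells and ADARB1 2091 CPM in YTHDF3-ADAR cells.

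The comparison of inputs asked which RNAs differed between the lines before any RIP. Beside the fusion genes, NPTX2 was higher in YTHDF1-ADAR cells than in the other lines, and FOXO4 and ZNF462 were higher in YTHDF3-ADAR cells than in the others. NPTX2 encodes a neuronal pentraxin, FOXO4 a forkhead factor and ZNF462 a zinc finger protein of development. Between YTHDF1-ADAR and YTHDF2-ADAR inputs, 4246 genes were higher and 1368 lower. They included YTHDF1 (2.85 ± 0.20), ADARB1 (3.16 ± 0.21), NPTX2 (3.65 ± 0.20) and ASMTL (3.76 ± 0.23). On the lower side lay YTHDF2 (-1.06 ± 0.18) and CALCB (-1.44 ± 0.19). ASMTL overlaps ASMTL-AS1 (3.61 ± 0.25), and MIR3648-1 (4.47 ± 1.09) and MIR3648-2 (4.66 ± 1.10) are copies of one another, so counts could not be assigned to either partner. MIR3648 took 5.63 percent of counts in replicate 1 of the YTHDF1-ADAR inputs and 0.0328 to 0.304 in the other 8 inputs, so its rise is that of 1 library. CDR1 (-1.84 ± 0.58) lies opposite LINC00632 (-1.41 ± 0.48) and is uncertain for the same reason. Against YTHDF3-ADAR inputs, 3609 genes were higher in YTHDF1-ADAR cells and 1624 lower. These included YTHDF1 (2.75 ± 0.20), NPTX2 (3.58 ± 0.20) and ASMTL (3.69 ± 0.23), and as lower FOXO4 (-2.80 ± 0.23), ZNF462 (-2.78 ± 0.33), ADARB1 (-2.01 ± 0.20) and YTHDF3 (-1.21 ± 0.17). Between YTHDF2-ADAR and YTHDF3-ADAR inputs the split was 403 higher and 685 lower (1088 in all, and 586 to 677 with any of these 6 inputs left out), led by FBXL16 (2.06 ± 0.22), ZNF426 (1.55 ± 0.13) and YTHDF2 (0.70 ± 0.18). The lower side held ADARB1 (-5.17 ± 0.23), ZNF462 (-3.56 ± 0.35), FOXO4 (-2.98 ± 0.23), SYT14 (-1.79 ± 0.21), KANK1 (-1.62 ± 0.15) and YTHDF3 (-1.16 ± 0.17).

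By list, the small structured noncoding RNAs (snRNAs, snoRNAs, Y RNAs and others) were higher in YTHDF1-ADAR inputs than in YTHDF2-ADAR inputs (141 higher and 2 lower of 715, median 1.11, adjusted p = 1.68e-09; adjusted p = 0.509 with an estimated correlation), with SNORD57 at 2.19 and RNU6-800P at 6.05. The snoRNA share was highest in the same replicate 1 (0.348 percent, against 0.0943 to 0.235 in the other 8 inputs), so this difference is not given as a trait of the line. ZNF zinc finger genes, many of them repressors of transcription, split 65 higher and 19 lower of 478 in YTHDF2-ADAR against YTHDF3-ADAR inputs (median 0.18, adjusted p = 9.46e-08; adjusted p = 0.182 with an estimated correlation), with ZNF91 at -2.88 ± 0.22 and ZNF804A at -7.82 ± 0.56. Adjusted over the list alone, these splits were 155 and 2, and 101 and 26. Of 15, 16 and 5 lists called in the 3 input comparisons, 1 held with an estimated correlation: blood cell markers in YTHDF2-ADAR against YTHDF3-ADAR cells (0 higher and 2 lower of 3, median -1.16, adjusted p = 0.0179 with an estimated correlation), carried by HBA1 (-1.16) and its near copy HBA2 (-1.20). The counts against YTHDF1-ADAR inputs rested on 1 library: without its replicate 1 they were 1093 against YTHDF2-ADAR and 1095 against YTHDF3-ADAR inputs.

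Before the RIP comparisons, the libraries were set against one another. The 6 YTHDF1 RIP libraries of the YTHDF2-ADAR and YTHDF3-ADAR cells stood apart from the other 30 in the kinds of RNA they held. These 6 libraries held more small nucleolar RNA, long noncoding RNA, mitochondrial mRNA and olfactory receptor sequence, the last being genes that these cells are not known to use. Protein-coding genes took 54.1 to 74.2 percent of their counts, against 86.1 to 88.0 in YTHDF1 RIP of YTHDF1-ADAR cells, 82.8 to 91.8 in YTHDF2 RIP, 90.0 to 92.4 in YTHDF3 RIP and 71.5 to 79.1 in inputs. The snoRNA share was 0.696 to 4.35 percent against 0.0360 to 0.564 in the other 30 libraries, the mitochondrial mRNA share 3.15 to 8.58 against 0.561 to 3.06, and olfactory receptor genes took 32.3 to 54.3 CPM against 2.82 to 18.5. Their counts averaged 14.5 M, against 28.8 M in the others. On the first axis of a principal component analysis (70.5 percent of variance over 5000 genes) they lay from -172 to -151. Input replicate 1 of YTHDF1-ADAR cells (-84.4) and YTHDF2 RIP replicate 3 of the same cells (-86.0) lay next to them.

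**Figure D2:**
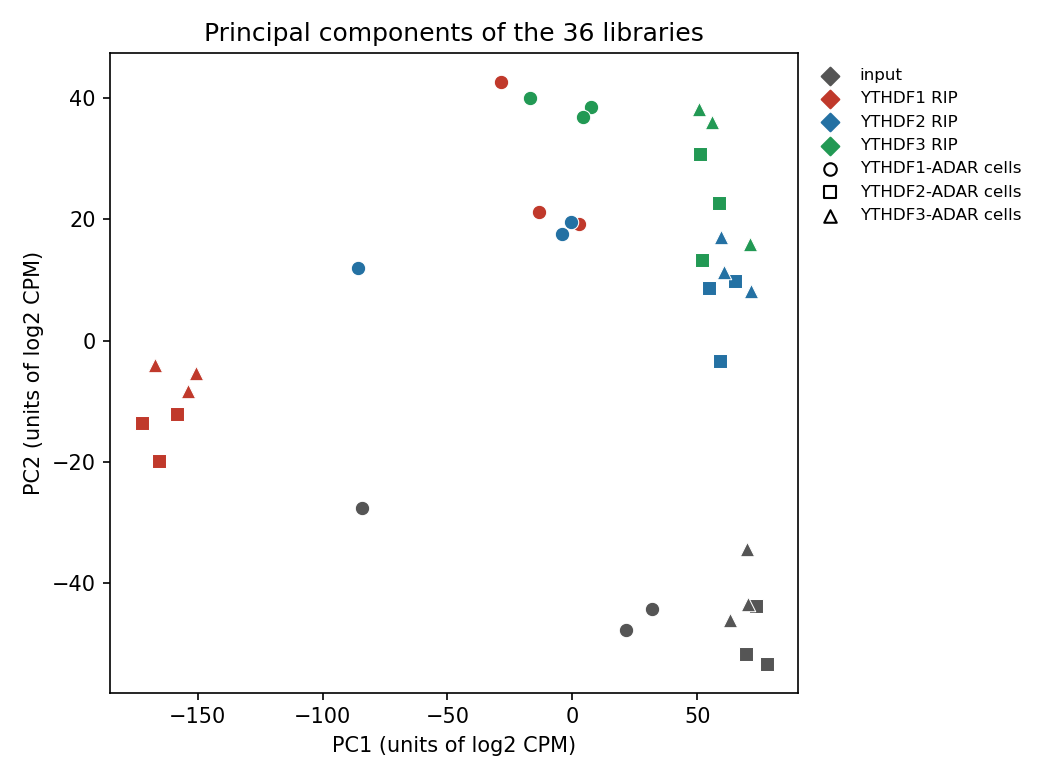
The 36 libraries on the first 2 principal components of log2 CPM over 5000 genes, in units of log2 CPM, coloured by RIP and with a marker for each cell line. Each point is a library. The first axis holds 70.5 percent of the variance and sets 6 YTHDF1 RIP libraries (-172 to -151) apart.

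YTHDF1 RIP against input asked which RNAs were recovered with YTHDF1, averaged over the 3 lines (9 against 9 libraries). The mitochondrial tRNAs MT-TG, MT-TL2, MT-TH, MT-TS2 and MT-TR, the imprinted antisense transcript KCNQ1OT1 and the list of olfactory receptor genes were higher, and short housekeeping mRNAs of ribosomes, mitochondria and the proteasome were lower. No list call held with an estimated correlation (smallest adjusted p = 0.139), and olfactory receptor sequence was high in the 6 libraries that stand apart (32.3 to 54.3 CPM, against at most 18.5). Signal recognition particle RNA, which docks ribosomes at the endoplasmic reticulum, was among the lowest. The average joins lines that differed strongly, as the next comparison shows. Of 31849 genes, 14248 were higher and 10321 lower, 9608 and 4961 of them by at least 2-fold. YTHDF1 itself (0.10 ± 0.11, adjusted p = 0.381) and YTHDF2 (-0.05 ± 0.10, adjusted p = 0.677) were not called on average, while YTHDF3 (0.50 ± 0.10), ADARB1 (1.02 ± 0.11), SON (0.39 ± 0.12) and CREBBP (0.73 ± 0.10) were higher. By line, in the order YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR, ADARB1 was at 2.42, 1.71 and -1.06 and CREBBP at 1.82, 0.09 and 0.28, ADARB1 being called lower in the last line and CREBBP called in the first only. ADAR (-0.34 ± 0.09), METTL3 (-0.35 ± 0.08), METTL14 (-0.21 ± 0.08), MYC (-0.68 ± 0.10), ACTB (-1.42 ± 0.13), HPRT1 (-2.21 ± 0.12), GAPDH (-2.79 ± 0.16) and RPL30 (-2.60 ± 0.13) were lower. Scaled to mitochondrial mRNAs, YTHDF3 (-0.62), ADARB1 (-0.16), SON (-0.78) and CREBBP (-0.43) changed sign, as did METTL14 (0.14) by total counts. The largest rises among genes named by rule were TMPRSS9 (4.70 ± 0.26; ENSG00000178297, chr 19 2360238 to 2426239), a serine protease gene, MT-TG (3.85 ± 0.24), KCNQ1OT1 (3.55 ± 0.34; ENSG00000269821, chr 11 2608328 to 2699994) and LINC00342 (3.48), beside MT-TL2 (3.49), MT-TH (3.44), MT-TS2 (3.41) and MT-TR (3.37). The lowest were the 7SL copies RN7SL3 (-4.71 ± 0.34), RN7SL2 (-4.53), RN7SL1 (-4.31 ± 0.31; ENSG00000276168, chr 14 49586580 to 49586878) and their pseudogenes RN7SL4P (-4.69) and RN7SL5P (-4.69), which share reads. RPL39P3 (-4.10 ± 0.27), a pseudogene that shares its sequence with RPL39, COX8A (-3.62 ± 0.19; ENSG00000176340, chr 11 63974620 to 63976543) and RPPH1 (-3.54 ± 0.35) followed.

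In lists fixed before the data were examined, all 83 cytosolic ribosomal protein genes were lower (median -2.15, adjusted p = 3.75e-31; adjusted p = 0.151 with an estimated correlation), with RPS13 at -3.20 ± 0.13, RPS21 at -3.51 ± 0.14 and RPL34 at -2.67 ± 0.11. Nuclear-encoded oxidative phosphorylation genes (10 higher and 77 lower of 95, median -1.79, adjusted p = 1.87e-20; adjusted p = 0.139 with an estimated correlation) included COX7A2 (-3.30 ± 0.12), COX5B (-3.001 ± 0.12) and COX7C (-3.20 ± 0.14), and the list also holds pseudogenes such as ATP5PBP1 and ATP5MFP6. Mitochondrial ribosomal proteins (1 higher, 77 lower of 78, median -1.43) with MRPL47 (-2.76 ± 0.13), proteasome subunits (0 and 33 of 35, median -1.35) with PSMB4 (-2.12 ± 0.10) were lower as lists. The same held for translation initiation factors (20 and 67 of 98, median -1.06) with EIF6 (-2.20) and replication-dependent histones (0 and 44 of 55, median -1.504) with H2AC20 (-2.61 ± 0.17). Secretory pathway genes (0 and 40 of 41, median -1.61) with SSR3 (-2.70 ± 0.10) and TMED10 (-2.48 ± 0.10) and low-m6A control mRNAs (0 and 8 of 8, median -2.67) with RPS28 (-3.09 ± 0.16) were lower. So were snoRNA host genes (4 and 18 of 29, median -0.51) with SNHG5 (-1.48 ± 0.12) and CCR4-NOT and P-body genes (7 and 21 of 36, median -0.42) with CNOT7 (-1.52). Stress granule genes (1 and 14 of 18, median -0.61) with PABPC1 (-1.53), G2/M genes (3 and 21 of 25, median -0.86) with CDK1 (-1.98) and S phase genes (4 and 27 of 31, median -0.77) with PCNA (-1.78) were lower as well. Higher as lists were small structured noncoding RNAs (484 and 55 of 715, median 1.41) with SNORA7B (2.35 ± 0.21) and olfactory receptor genes (27 and 1 of 34, median 2.82) with OR10A2 (4.65 ± 0.39). Nuclear long noncoding RNAs (8 and 1 of 10, median 1.22) with MALAT1 (1.45 ± 0.26) and mitochondrially encoded mRNAs (8 and 0 of 13, median 0.81) with MT-ND5 (2.46 ± 0.21) were higher. So were ZNF genes (273 and 73 of 478, median 0.31) with ZNF780B (1.91 ± 0.11) and chromatin coregulators (34 and 6 of 50, median 0.39) with ARID1B (1.29 ± 0.08) and CHD7 (1.18 ± 0.09). All 19 list calls were lost with an estimated correlation, where the smallest adjusted p = 0.139. No list call was made for m6A writers, erasers and readers (4 and 9 of 21, median -0.13, adjusted p = 0.0858), mRNAs described as m6A-modified (7 and 10 of 22, median -0.05, adjusted p = 0.359) or immediate-early genes (4 and 7 of 22, median -0.05, adjusted p = 0.359). Interferon-stimulated genes (7 and 3 of 14, median 0.26, adjusted p = 0.593) and blood (1 and 2 of 3, median -2.03), fibroblast (1 and 4 of 7, median -0.59) and epithelial markers (1 and 2 of 3, median -0.93) were not called either. Adjusted over each list alone, the counts differed by at most 1 gene. Under total-count scaling or DESeq2 size factors the medians of the m6A writer, m6A-modified and immediate-early lists changed sign, and under scaling to mitochondrial mRNAs so did those of ZNF genes (-0.82), coregulators (-0.80), interferon-stimulated genes (-0.93) and the mitochondrial mRNAs (-0.23). The median over all genes was 0.25 by TMM, 0.40 by DESeq2, 0.58 by total counts and -0.91 by mitochondrial mRNAs, where the split was 3857 higher and 18061 lower, against 17948 and 7465 by total counts.

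Whether YTHDF1 RIP enrichment differed between the lines was tested as an interaction. The messages of YTHDF1, ADAR and MYC were higher with YTHDF1 in YTHDF1-ADAR cells and lower in the other lines, while small structured noncoding RNAs went the other way. The YTHDF1 RIP libraries of the other lines are the 6 that stand apart (snoRNA 0.696 to 4.35 percent, against at most 0.564). A difference in binding between lines cannot be told apart from a difference of these libraries. ADO encodes a thiol dioxygenase, F2R the thrombin receptor, and BCL2, SOX4 and JUN are short-lived or regulated messages. The interaction called 20300 genes, with ADO (adjusted p = 2.71e-16), ENDOD1 (2.71e-16), PGAP4 (3.63e-16), F2R (3.77e-16) and RAP2B (4.44e-16) first; enrichment of ADO was 3.64 higher in YTHDF1-ADAR cells than in the other lines. For YTHDF1 the enrichment was 2.33, -0.98 and -1.04 in YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR cells, for YTHDF3 1.97, -0.16 and -0.31, for MYC 1.12, -1.61 and -1.53, for SON 1.77, -0.25 and -0.36, and for ADAR 1.01, -0.998 and -1.02. Between YTHDF2-ADAR and YTHDF3-ADAR cells 2 genes differed (1088 at an unadjusted p under 0.05).

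In YTHDF1-ADAR cells alone, YTHDF1 RIP held 6569 genes higher and 9186 lower than input. TMPRSS9 (3.41 ± 0.42), CCDC71 (2.85 ± 0.27), TMEM121 (2.83 ± 0.26), FKBPL (2.76 ± 0.22) and GEMIN7 (2.91 ± 0.22, overlapping GEMIN7-AS1 at 2.85) led, and RN7SL4P (-4.70), RPS21 (-3.83 ± 0.25) and RNU1-2 (-3.64) were lowest among them. ZNF genes (343 higher and 34 lower of 478, median 1.00, adjusted p = 1.69e-27) were the list call that also held with an estimated correlation (adjusted p = 0.00106), with ZNF14 at 2.36 ± 0.16, ZNF555 at 2.14 and ZNF12 at 1.84. Adjusted over the list alone, ZNF genes split 348 and 35 and small structured noncoding RNAs 8 and 250. mRNAs described as m6A-modified (15 and 1 of 22, median 1.05, adjusted p = 3.47e-07; adjusted p = 0.148 with an estimated correlation) with BCL2 (2.24 ± 0.14), SOX4 (2.06 ± 0.18) and TRIB1 (1.83) were higher. So were immediate-early genes (14 and 0 of 22, median 0.76, adjusted p = 7.98e-06; adjusted p = 0.148 with an estimated correlation) with IER5 (2.29 ± 0.22), JUNB (2.14) and JUN (1.69), and coregulators (40 and 2 of 50, median 0.86, adjusted p = 2.92e-13; adjusted p = 0.148 with an estimated correlation) with ARID1A (1.82). Ribosomal protein genes stayed lower (0 and 74 of 83, median -2.15, adjusted p = 2.66e-25; adjusted p = 0.192 with an estimated correlation), and small structured noncoding RNAs, higher on average, were lower here (11 and 266 of 715, median -1.25, adjusted p = 0.00018; adjusted p = 0.339 with an estimated correlation). Input replicate 1 of these cells held the highest snoRNA share of the inputs (0.348 percent, against 0.0943 to 0.235 in the other 8). The lower small structured RNAs are therefore not given as a trait of the line. Across lines, the difference in enrichment was called with an estimated correlation for ZNF genes (316 and 50, median 1.09, adjusted p = 0.0147 with an estimated correlation) and small structured noncoding RNAs (10 and 622, median -3.88, adjusted p = 0.0496 with an estimated correlation). The other lines are read there in the 6 libraries that stand apart (snoRNA 0.696 to 4.35 percent), so lines and libraries cannot be told apart.

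**Figure D3:**
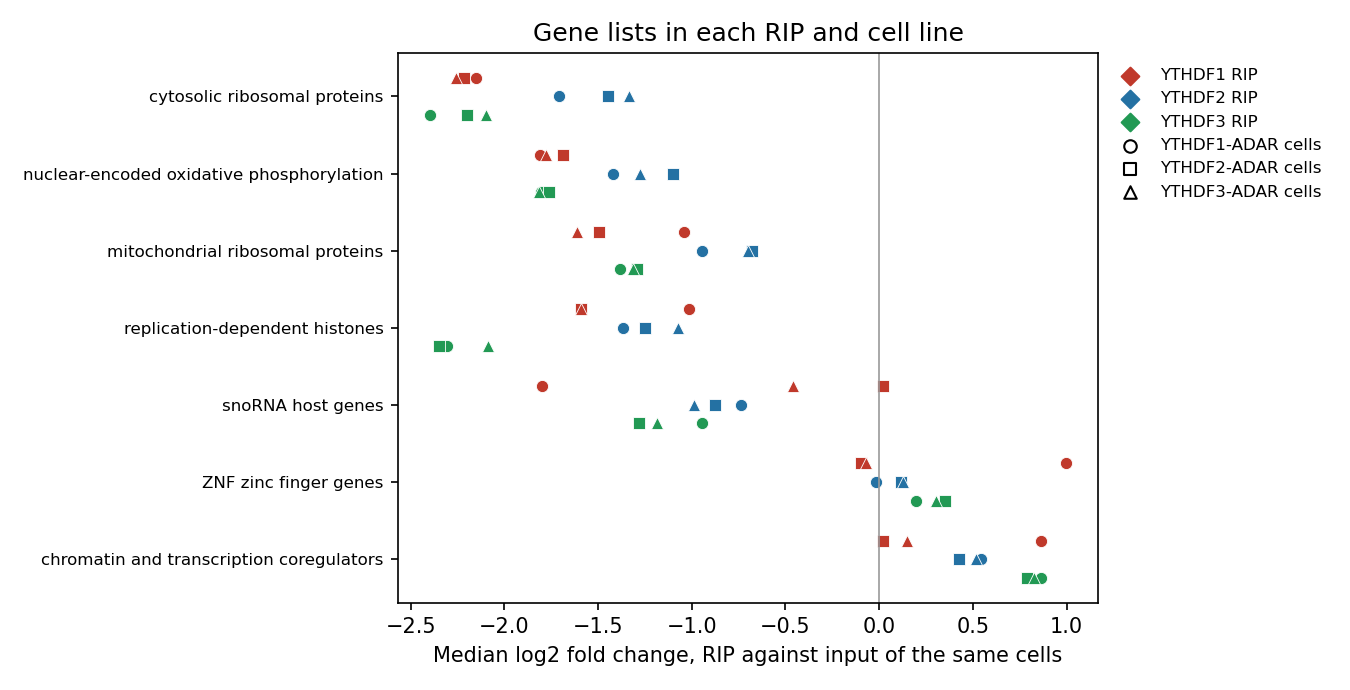
Median log2 fold change of RIP against input for 7 gene lists, by RIP and cell line; each point is the median of a list over its measured genes. Cytosolic ribosomal protein genes lay below 0 (averages over lines -2.15, -1.52 and -2.22), and ZNF genes reached 1.00 in YTHDF1 RIP of YTHDF1-ADAR cells; the ZNF and coregulator averages for YTHDF1 RIP changed sign when scaled to mitochondrial mRNAs.

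YTHDF2 RIP against input asked the same for YTHDF2, the reader tied to mRNA decay through CCR4-NOT. Among the messages that rose most were those of DDIT4, F11R and TARDBP, while the lists of ribosomal proteins, the respiratory chain and small structured RNAs were lower, although no list call held with an estimated correlation (smallest adjusted p = 0.0841). DDIT4 encodes a stress-induced inhibitor of mTORC1, F11R a junction protein and TARDBP the RNA-binding protein TDP-43. Of the genes tested, 5704 were higher and 6952 lower, 409 and 2346 by at least 2-fold. YTHDF2 (0.66 ± 0.10), YTHDF1 (0.46 ± 0.11), YTHDF3 (0.38 ± 0.10), ADARB1 (0.64 ± 0.11), ADAR (0.55 ± 0.09), SON (0.49 ± 0.12) and CREBBP (0.57 ± 0.10) were higher. ACTB (-0.57 ± 0.13), GAPDH (-1.45 ± 0.15), HPRT1 (-0.79 ± 0.12) and RPL30 (-1.56 ± 0.12) were lower, and MYC (0.21, adjusted p = 0.0885) and MALAT1 (0.25, adjusted p = 0.491) were not called. The largest rises by the same rule were MRFAP1 (1.69 ± 0.16; ENSG00000179010, chr 4 6640091 to 6642745), F11R (1.55 ± 0.08; ENSG00000158769, chr 1 160995211 to 161021343), DDIT4 (1.502 ± 0.19; ENSG00000168209, chr 10 72273924 to 72276036), PSMD2 (1.47 ± 0.12), SLC18B1 (1.43 ± 0.11), ZNF778 (1.42 ± 0.11), COPRS (1.41 ± 0.14) and TARDBP (1.39 ± 0.15). MRFAP1 rose in each line (2.12, 1.63 and 1.33). RN7SL5P and RN7SL4P (both -6.98), RN7SL1 (-6.11 ± 0.34) and the U1 copies RNVU1-7 (-5.13 ± 0.48), RNU1-2 (-5.11) and RNVU1-18 (-5.10), which share reads, were lowest among genes named by rule.

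Chromatin coregulators, long mRNAs of nuclear regulators, were higher with YTHDF2 (42 and 0 of 50, median 0.50, adjusted p = 1.98e-16; adjusted p = 0.105 with an estimated correlation), with KDM5A (0.85 ± 0.08), NSD1 (0.82 ± 0.09) and TRRAP (0.76 ± 0.08). mRNAs described as m6A-modified (9 and 2 of 22, median 0.20, adjusted p = 0.024; adjusted p = 0.627 with an estimated correlation) included IER2 (1.04 ± 0.10), CTNNB1 (0.95 ± 0.12) and BCL2 (0.74 ± 0.08). CCR4-NOT and P-body genes (17 and 9 of 36, median 0.20) with TNKS1BP1 (0.89), and ZNF genes (157 and 106 of 478, median 0.07) with ZNF740 (0.96 ± 0.06) were also called higher. Ribosomal protein genes (0 and 81 of 83, median -1.52, adjusted p = 2.84e-48; adjusted p = 0.105 with an estimated correlation) with RPS21 (-3.19) and RPS13 (-2.87 ± 0.12) and oxidative phosphorylation genes (7 and 71 of 95, median -1.26, adjusted p = 9.09e-25; adjusted p = 0.0841 with an estimated correlation) with COX7A2 (-2.97 ± 0.12) and ATP5F1E (-2.69 ± 0.11) were lower. Mitochondrial ribosomal proteins (2 and 63 of 78, median -0.80) with MRPL13 (-2.03), histones (0 and 47 of 55, median -1.26) with H2AC20 (-2.12) and snoRNA host genes (1 and 23 of 29, median -0.91) with SNHG5 (-1.79) were lower. So were low-m6A controls (0 and 7 of 8, median -1.47) with RPS14 (-2.41 ± 0.16) and small structured noncoding RNAs (12 and 160 of 715, median -0.29) with RNY4 (-7.49 ± 0.54). Proteasome subunits (5 and 19 of 35, median -0.37) and initiation factors (10 and 34 of 98, median -0.22) were lower as lists, although the subunit PSMD2 was among the highest genes and EIF3B rose (1.08). None of the 13 list calls held with an estimated correlation (smallest adjusted p = 0.0841). Adjusted over each list alone, small structured noncoding RNAs split 8 and 139, ZNF genes 161 and 115 and initiation factors 11 and 38. Secretory pathway genes (14 and 12 of 41) had a median of 0.05 but a mean of -0.09 (adjusted p = 0.997), and S phase genes (11 and 9 of 31) a median of -0.01 and a mean of 0.02 (adjusted p = 0.526). The split over all genes was 8521 higher and 4574 lower by total counts and 3293 and 1825 by mitochondrial mRNAs; the median of S phase genes was then 0.20 and 0.28, and that of initiation factors 0.05 by mitochondrial mRNAs.

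YTHDF3 RIP against input put the question to YTHDF3. Among the messages that rose most were those of PARP11, USB1, SIX2 and CDK12, while the lists of ribosomal proteins, the respiratory chain and small structured RNAs were lower, although no list call held with an estimated correlation (smallest adjusted p = 0.0539). PARP11 encodes a mono-ADP-ribosyltransferase, USB1 trims U6 RNA, SIX2 is a kidney progenitor factor and CDK12 is a transcription kinase. Of the genes tested, 6918 were higher and 8302 lower, 856 and 3687 by at least 2-fold. YTHDF3 (0.63 ± 0.10), YTHDF1 (0.59 ± 0.11), ADAR (0.97 ± 0.09), ADARB1 (0.77 ± 0.11), METTL14 (0.52 ± 0.08), SON (1.09 ± 0.12) and CREBBP (0.87 ± 0.10) were higher. ACTB (-1.06 ± 0.13), GAPDH (-2.14 ± 0.15), HPRT1 (-1.76 ± 0.12), RPL30 (-2.72 ± 0.13) and MALAT1 (-0.63 ± 0.26) were lower. YTHDF2 (0.16, adjusted p = 0.203) and MYC (0.07, adjusted p = 0.606) were not called. By that rule the largest rises were PARP11 (1.83 ± 0.12; ENSG00000111224, chr 12 3791047 to 3873448), USB1 (1.82 ± 0.13; ENSG00000103005, chr 16 57999546 to 58021618), SIX2 (1.79 ± 0.12; ENSG00000170577, chr 2 45005182 to 45009452), CCDC97 (1.60 ± 0.08), SBK1 (1.56 ± 0.11), CDK12 (1.54 ± 0.12), SEC14L1 (1.53 ± 0.11) and CDR1 (1.71 ± 0.33), which lies in the LINC00632 locus and is uncertain. RN7SL4P (-7.90 ± 0.47) and RN7SL1 (-7.00 ± 0.35), which share reads, RPPH1 (-5.22 ± 0.38) and RMRP (-4.87 ± 0.44) were lowest among genes named by rule.

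Coregulators were higher with YTHDF3 (49 and 0 of 50, median 0.82, adjusted p = 1.65e-24; adjusted p = 0.0594 with an estimated correlation), with NSD1 (1.42 ± 0.09), KMT2C (1.15 ± 0.08) and KDM5A (1.12 ± 0.08). ZNF genes (238 and 54 of 478, median 0.28, adjusted p = 1.89e-08; adjusted p = 0.0659 with an estimated correlation) with ZNF709 (1.32 ± 0.09), CCR4-NOT and P-body genes (20 and 7 of 36, median 0.29) with CNOT1 (1.01 ± 0.09) and AGO2 (0.97 ± 0.07), and m6A writers, erasers and readers (11 and 4 of 21, median 0.36) with VIRMA (0.82 ± 0.11) and IGF2BP1 (0.79 ± 0.10) were also higher. Lower were ribosomal protein genes (0 and 80 of 83, median -2.22, adjusted p = 2.67e-43; adjusted p = 0.0659 with an estimated correlation) with RPS21 (-4.33 ± 0.15) and RPL34 (-3.14 ± 0.11) and oxidative phosphorylation genes (2 and 80 of 95, median -1.80, adjusted p = 3.74e-33; adjusted p = 0.0539 with an estimated correlation) with COX7A2 (-4.08 ± 0.13) and COX5B (-3.37). Mitochondrial ribosomal proteins (0 and 75 of 78, median -1.37) with MRPL52 (-2.15), proteasome subunits (3 and 28 of 35, median -0.88) with PSMB4 (-2.08 ± 0.10) and histones (0 and 52 of 55, median -2.20) with H2AC20 (-3.40 ± 0.17) were lower. So were snoRNA host genes (2 and 25 of 29, median -1.01) with SNHG5 (-2.62 ± 0.12) and low-m6A controls (0 and 8 of 8, median -2.23) with RPS28 (-3.17 ± 0.16). Small structured noncoding RNAs (36 and 205 of 715, median -0.42), secretory pathway genes (9 and 18 of 41, median -0.15) with SEC61G (-3.64 ± 0.16), S phase genes (6 and 17 of 31, median -0.38) and blood markers (0 and 2 of 3, median -2.46) completed the 15 list calls, none of which held with an estimated correlation (smallest adjusted p = 0.0539). mRNAs described as m6A-modified (7 and 6 of 22, median 0.06, adjusted p = 0.279) were not called, although BCL2 rose (0.82 ± 0.08). Nuclear long noncoding RNAs had a median of -0.07 with a test direction upward (adjusted p = 0.62; median 0.17 by total counts), and interferon-stimulated and G2/M genes had medians of 0.04 with means of -0.03 and -0.01. By total counts the split over all genes was 10478 and 5677, and by mitochondrial mRNAs 8886 and 2556, where the medians of secretory genes (0.38) and S phase genes (0.16) were above 0.

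YTHDF1 RIP against YTHDF2 RIP asked which RNAs the antibodies separated. Membrane and secreted protein messages were lower with YTHDF1, and small nucleolar and U1 RNAs were higher. No list call held with an estimated correlation (smallest adjusted p = 0.128), and snoRNA took most in the 6 libraries that stand apart (0.696 to 4.35 percent, against at most 0.564). SERINC1 and CD63 encode membrane proteins, and SCARNA5 guides modification of spliceosomal RNA. The split was 14372 higher and 9709 lower. SERINC1 (-3.58 ± 0.12; ENSG00000111897, chr 6 122443351 to 122471807), F11R (-3.18 ± 0.09), EI24 (-3.14 ± 0.14), COPRS (-3.10 ± 0.15) and ATP5F1A (-3.01 ± 0.12) were lower, the first in each line (-3.32, -3.78 and -3.65). TMPRSS9 (4.38 ± 0.26), SCARNA5 (4.03 ± 0.58; 1.00, 5.58 and 5.52 by line) and the U1 copies RNVU1-7 and RNVU1-29 (both 3.78) were higher. YTHDF2 (-0.70), MYC (-0.89), HPRT1 (-1.42) and RPL30 (-1.03) were lower on average, but in YTHDF1-ADAR cells alone MYC was higher (0.82) and YTHDF2 not called (0.25, adjusted p = 0.281). Secretory pathway genes (0 and 40 of 41, median -1.45, adjusted p = 5.95e-21; adjusted p = 0.128 with an estimated correlation) included CD63 (-2.99 ± 0.15) and PDIA6 (-2.72 ± 0.12). Small structured noncoding RNAs (575 and 10 of 715, median 1.83, adjusted p = 5.18e-11; adjusted p = 0.128 with an estimated correlation) included SNORA80D (3.45). S phase genes (0 and 25 of 31, median -0.81), proteasome subunits (2 and 30 of 35, median -0.97) and m6A writers, erasers and readers (2 and 13 of 21, median -0.36, adjusted p = 0.00663; adjusted p = 0.422 with an estimated correlation) with IGF2BP1 (-1.71) were lower too, and none of the 18 list calls held with an estimated correlation. In YTHDF1-ADAR cells alone the split was 6451 and 5996, and ZNF genes were higher (367 and 14 of 478, median 1.05, adjusted p = 2.49e-35; adjusted p = 0.000197 with an estimated correlation). By mitochondrial mRNAs the average split was 2558 and 18819, and the median over all genes was 0.27 by TMM and 0.41 by DESeq2.

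YTHDF1 RIP against YTHDF3 RIP gave a like picture. On average over lines, membrane protein and RNA decay messages were lower with YTHDF1, and U3 snoRNA copies and histone messages were higher. No list call held with an estimated correlation (smallest adjusted p = 0.161), and the histone median turned to -0.84 by mitochondrial mRNAs. The average includes the 6 libraries that stand apart (snoRNA 0.696 to 4.35 percent). MYADM encodes a membrane protein and UCP2 a mitochondrial carrier. The split was 14771 higher and 9131 lower, with MYADM (-3.66 ± 0.12), UCP2 (-3.54 ± 0.12), APOOL (-3.52 ± 0.11), DDAH1 (-3.41 ± 0.10) and USB1 (-3.08 ± 0.14) lowest. MIR663AHG (5.81 ± 0.82) and the U3 copies SNORD3D (5.80 ± 0.62), SNORD3B-1 (5.56) and SNORD3B-2 (5.42) were highest. Secretory genes (2 and 37 of 41, median -1.24, adjusted p = 4.29e-16; adjusted p = 0.161 with an estimated correlation) with TMED10 (-2.89 ± 0.10), coregulators (3 and 35 of 50, median -0.49, adjusted p = 4e-08; adjusted p = 0.168 with an estimated correlation) with SMARCC1 (-1.34), and CCR4-NOT genes (4 and 26 of 36, median -0.52) were lower. Histones (40 and 2 of 55, median 0.83) with H2AC13 (1.77) and small structured noncoding RNAs (570 and 12 of 715, median 1.998) were higher; none of the 15 list calls held with an estimated correlation. Ribosomal protein genes had a median of 0.14 with a test direction downward (35 and 24 of 83, adjusted p = 0.694). In YTHDF1-ADAR cells alone the split was 7143 and 5944, and by mitochondrial mRNAs the average split was 2609 and 20351, with a median of -1.52 for ribosomal protein genes.

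YTHDF2 RIP against YTHDF3 RIP set the readers with like profiles side by side. Respiratory chain, ribosomal and histone messages were higher with YTHDF2, and coregulator and zinc finger messages with YTHDF3, although no list call held with an estimated correlation (smallest adjusted p = 0.360). The split was 6273 higher and 5412 lower. The copies of 5.8S rRNA RNA5-8SN4 (3.61 ± 0.50) and RNA5-8SN5 (3.56 ± 0.49) were highest and the U1 copies RNVU1-7 (-3.12 ± 0.44) and RNU1-1 (-3.05) lowest, all sharing reads. CD63 (2.45 ± 0.14), ATP5MG (2.95 ± 0.15), H4C8 (2.29), RPL30 (1.16), HPRT1 (0.97), IER2 (1.30) and CTNNB1 (0.88) were higher with YTHDF2. ZNF391 (-1.97), ZNF100 (-1.44), TMED10 (-1.13), METTL14 (-0.85), NCOA3 (-0.68), KMT2A (-0.60) and SON (-0.61) were higher with YTHDF3. Oxidative phosphorylation genes (59 and 4 of 95, median 0.63, adjusted p = 6.01e-13; adjusted p = 0.36 with an estimated correlation), ribosomal protein genes (57 and 2 of 83, median 0.66, adjusted p = 7.53e-12; adjusted p = 0.494 with an estimated correlation) and histones (42 and 0 of 55, median 1.12) were higher. Coregulators (1 and 37 of 50, median -0.37, adjusted p = 3.51e-11; adjusted p = 0.36 with an estimated correlation) and ZNF genes (66 and 192 of 478, median -0.20) were lower. Adjusted over each list alone, oxidative phosphorylation and ribosomal protein genes each split 61 and 5 and ZNF genes 72 and 198. None of the 14 list calls held with an estimated correlation, and by mitochondrial mRNAs the split was 996 and 2860.

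Whether enrichment differed among the lines was asked by interaction for YTHDF2 and YTHDF3 as well. For YTHDF2 edgeR's quasi-likelihood test called 0 genes (1064 at an unadjusted p under 0.05; DESeq2 called 3), with SEC14L1 first (adjusted p = 0.119). For YTHDF3 it called 2 (1632 at an unadjusted p under 0.05, while DESeq2 called 6), and 0 with a block for replicate number. SEC14L1 (adjusted p = 0.0173; ENSG00000129657, chr 17 77088749 to 77217101), which encodes a lipid-binding protein that damps antiviral signalling, was enriched by 0.57, 2.31 and 1.72 in YTHDF1-ADAR, YTHDF2-ADAR and YTHDF3-ADAR cells. It thus stood lowest in YTHDF1-ADAR cells, not apart in the YTHDF3-ADAR line. HSBP1L1, named after its value was seen, was the other (adjusted p = 0.0478). With each library left out in turn the count for YTHDF3 ranged from 0 to 4, and it was 0 without YTHDF3-ADAR input replicate 1, 2 or 3 or YTHDF3-ADAR YTHDF3 RIP replicate 1 or 2, among others. The line of the same fusion against the others called 0 genes for YTHDF2 RIP (822 at an unadjusted p under 0.05) and 0 for YTHDF3 RIP (835) by edgeR's quasi-likelihood test. On data simulated for these interactions with 28404 genes, edgeR called 0 of 67 genes changed 1.5-fold for each RIP, 16 and 13 of 67 changed 2-fold and 36 of 66 changed 4-fold, so low counts do not show that enrichment was equal.

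Genes shared by the RIPs were counted to see which RNAs moved with all 3 proteins. At least 2-fold in each RIP, 69 genes were higher and 1334 lower, where independent lists of these sizes would share 3.32 and 42.3. With YTHDF1 RIP of YTHDF1-ADAR cells only, these were 33 and 1366. With each RIP set against its own share of the inputs, which also leaves fewer inputs for each RIP, 21 to 52 genes were higher and 970 to 1156 lower in all 3, where independent lists would share 4.38 to 10.7 and 25.6 to 28.8. RPS13, RPS21, COX7A2, H2AC20 and RPL30 were lower by over 2-fold in each RIP against the full inputs. Across genes, which are not independent replicates, the fold changes of YTHDF2 and YTHDF3 RIP had a correlation of 0.71, where simulated RIPs without any change gave 0.52 through the inputs they share, and separate inputs gave 0.45 to 0.58. For YTHDF1 RIP with YTHDF2 and YTHDF3 RIP it was 0.45 and 0.43, where 0.46 and 0.47 were simulated without change. Separate inputs gave 0.32 to 0.57 and 0.31 to 0.56 there, and the covariances, 0.504 and 0.569, lay above the 0.0663 and 0.0660 simulated.

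The authors' deposited tables of edited genes were read for the TRIBE part of the design, to see which genes were listed in each line. They list editing per gene, pooled over replicates, and are described here without a test of their own. Every group expressed a fusion, so the sites cannot be credited to the fusions alone. In YTHDF1-ADAR cells the authors' deposited table held 7829 genes and 127931 sites, in YTHDF2-ADAR cells 2402 genes and 6515 sites, and in YTHDF3-ADAR cells 2944 genes and 9181 sites; 1439 genes were in all 3. Among genes that the authors' deposited table lists in all 3 lines, sites summed over the lines were most numerous in FAT1, a giant cadherin gene (351), FOXK1 (330), PUSL1 (319), KMT2D (314) and ZNF276 (269). YTHDF1-ADAR cells gave 332, 287, 312, 306 and 249 of these sites in the authors' deposited table, so this line supplied most of them. In YTHDF1-ADAR cells the median editing level computed from the authors' deposited table was 2.50 percent in input and 3.71, 3.39 and 3.18 in YTHDF1, YTHDF2 and YTHDF3 RIP. In YTHDF2-ADAR cells it was 0.942 percent in input and 0.505, 0.928 and 1.19 in the RIPs, and in YTHDF3-ADAR cells 1.11, 0.511, 1.01 and 1.35. The 0.505 and 0.511 come from the 6 libraries of lower depth that stand apart, where the authors' deposited table has 922 of 2199 and 1169 of 2763 genes at 0, against 294 and 278 in input. Mean levels there were 2.36 percent (2.41 in input) in YTHDF2-ADAR and 2.03 (2.46 in input) in YTHDF3-ADAR cells, from the authors' deposited table. Of genes whose level differed from input, with ties left out, levels were above it in 83.2, 78.5 and 76.1 percent of genes in YTHDF1-ADAR cells, in 34.8, 50.2 and 59.5 in YTHDF2-ADAR cells and in 30.01, 47.0 and 59.2 in YTHDF3-ADAR cells, again from the authors' deposited table.

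**Figure D4:**
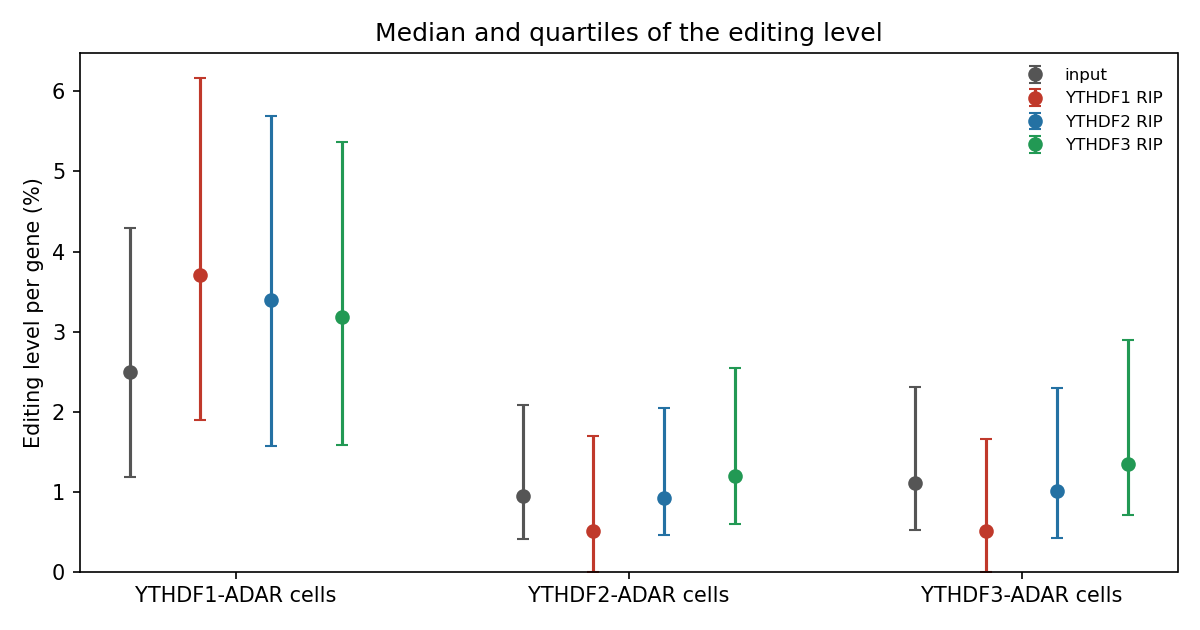
Editing level in percent per gene, computed from the authors' deposited tables, for input and each RIP in the 3 cell lines; points are medians over genes and bars the quartiles. YTHDF1-ADAR cells had medians of 2.50 to 3.71 percent, and YTHDF1 RIP had the lowest medians in the other lines (0.505 and 0.511), in the 6 libraries of lower depth that stand apart.

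Genes whose editing rose in the RIP included C3orf62, CPEB1, SDHC and PARP1. CPEB1 encodes a cytoplasmic polyadenylation protein, SDHC a membrane anchor of succinate dehydrogenase and PARP1 a DNA damage enzyme. The authors' deposited table gives C3orf62 at 9.72 percent in input and 54.2 in YTHDF1 RIP of YTHDF1-ADAR cells (the authors' adjusted p = 0.000127). In the same cells, the authors' deposited table gives CPEB1 at 30.9 and 74.3 percent in YTHDF2 RIP (adjusted p = 0.00249) and SDHC at 6.29 and 25.3 in YTHDF3 RIP (adjusted p = 7.24e-11). MYC, with 19 sites, went from 2.98 to 3.90 percent in YTHDF1 RIP (adjusted p = 0.0107) in the authors' deposited table, and SON, with 156 sites, from 7.92 to 9.83 (adjusted p = 0.377). In YTHDF2-ADAR cells YTHDF1 RIP held PARP1 at 94.8 percent (adjusted p = 2.99e-07), HNRNPA2B1 at 77.6 against 14.9 in input (adjusted p = 1.89e-29) and RPL3 at 92.0 against 16.7, per the authors' deposited table. In YTHDF3-ADAR cells the authors' deposited table gives SF1 at 12.9 percent in input and 95.3 in YTHDF1 RIP (adjusted p = 1.93e-17) and MBD4 at 20.1 in input and 43.5 in YTHDF3 RIP. In the authors' deposited table the values of C3orf62, CPEB1, SDHC, PARP1 and MBD4 each rest on 1 site, and those of HNRNPA2B1, RPL3 and SF1 on 2. PARP1, HNRNPA2B1, RPL3 and SF1 were read in the 6 libraries that stand apart, where in the authors' deposited table more genes lay below input (1307 and 1791) than above it (698 and 768). The authors' deposited table calls 621 genes higher and 15 lower in YTHDF1 RIP of YTHDF1-ADAR cells, 126 and 2 in YTHDF2 RIP and 79 and 9 in YTHDF3 RIP. In YTHDF2-ADAR cells the authors' deposited table calls 48 and 13, 0 and 5, and 20 and 11 in the same order, and in YTHDF3-ADAR cells 62 and 17, 2 and 1, and 46 and 8.

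Edited genes were then compared with the RIP counts, to ask whether edited messages were also recovered with the protein. Genes in the authors' deposited table for YTHDF1-ADAR cells had a median YTHDF1 RIP fold change of 0.23 in those cells (7747 genes), against -1.04 for genes not listed that matched in exon length and input level. For YTHDF2 in YTHDF2-ADAR cells the medians were 0.13 (2318 genes of the authors' deposited table) and 0.12, and for YTHDF3 in YTHDF3-ADAR cells 0.19 (2849 genes) and 0.05.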

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

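The tests of another cell line, of a background profile and of a batch behind the 6 YTHDF1 RIP libraries were chosen after those libraries had been seen. Tests against lists of short genes and among the most abundant genes were chosen after a first matched test of the same pattern was seen.

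YTHDF1 RIP enrichment differed between lines for 20300 genes, and YTHDF3 RIP enrichment for 2, by tests of the difference itself. The first genes for YTHDF1 were ADO (adjusted p = 2.71e-16), ENDOD1 (2.71e-16), PGAP4 (3.63e-16), F2R (3.77e-16) and RAP2B (4.44e-16), and for YTHDF3 SEC14L1 (0.0173). The count of 2 for YTHDF3 was 0 with only the libraries compared, and 0 to 4 with each library left out in turn (0 without YTHDF3-ADAR input replicate 1, 2 or 3, among others). Taking YTHDF1-ADAR cells against the other lines, the median difference in YTHDF1 RIP enrichment was 1.09 for ZNF genes, 1.91 for mRNAs described as m6A-modified and 1.84 for immediate-early genes, and -3.88 for small structured noncoding RNAs, -1.44 for snoRNA host genes and -4.27 for olfactory receptor genes. With an estimated correlation the ZNF (adjusted p = 0.0147) and small structured RNA (0.0496) calls held, and those of m6A-modified mRNAs (0.139), immediate-early (0.143), snoRNA host (0.429) and olfactory receptor genes (0.471) were lost. The rat Apobec1 sequence averaged 2.41 CPM in the 6 YTHDF1 RIP libraries that stand apart and 0.0573 in inputs.

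These 6 libraries were the first pattern weighed. Their lower depth was argued against: with every library thinned to the lowest total, 17247 genes differed between lines, against 20300 before. A swap of lines was argued against as well, since 6 of 6 lay nearest to their own line by the levels of YTHDF1, YTHDF2, YTHDF3 and ADARB1. A background profile stays open, because input replicate 1 of YTHDF1-ADAR cells, which saw no antibody, deviated from its fellow inputs in the same direction (correlation across coding genes, which are not independent replicates, 0.720 with the effect in 1 line and 0.764 in the other, against 0.365 with YTHDF1 RIP of YTHDF1-ADAR cells), although YTHDF2 RIP replicate 3 of the same cells, which lay next to it on the first principal component, reached only 0.304 and 0.305. A separate library batch stays open too, with Apobec1 at 1.35 CPM or more in the 6 and at most 0.687 in the other 30, and a biological effect of the YTHDF1 fusion on the RIP, which the design names, was not tested apart from these.

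The second pattern was that ribosomal protein and oxidative phosphorylation mRNAs were lower than input in all 3 RIPs. The inputs that the RIPs share were argued against, since with separate inputs the medians stayed at -1.34 or lower for ribosomal proteins and -1.14 or lower for oxidative phosphorylation. A first test, against lists matched on whole exon length and expression, put both lists at percentile 0 in all 3 RIPs (medians -2.15, -1.52 and -2.22 for ribosomal proteins against -1.47, -0.23 and -0.58 matched, and -1.84, -1.36 and -1.99 against -1.09, -0.29 and -0.62 for coding oxidative phosphorylation genes), which argues against whole exon length as the cause. Whole exon length sums all annotated exons (median 3188 bases for ribosomal proteins) and is not the length of the mRNA, so short transcripts stay open: among 10000 lists of short coding genes of like expression, the ribosomal protein median lay at percentiles 1.77, 0 and 28.0 for YTHDF1, YTHDF2 and YTHDF3 RIP, so that this explanation cannot be told apart from others for that list, and the oxidative phosphorylation median at 24.1, 0.04 and 45.8. A lower m6A content of these mRNAs, or their tighter hold on ribosomes, was not tested, as no group of the design changes either. The short genes drawn for a list could include members of the other list, since only its own members were left out. Those drawn for ribosomal proteins also lay lower in input (8.20 against 8.74 log2 CPM). The percentiles among short genes therefore cannot weigh short length alone.

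The third pattern was that genes listed as edited were higher in the RIP than matched genes that were not. In YTHDF1-ADAR cells the difference in medians was 1.26, and among the genes most abundant in input it was 1.07. The matched abundant genes still held fewer reads (median counts per gene and RIP library 1352, against 2942 for listed genes). The test therefore cannot decide whether edited sites were found because the RIP held more reads. In YTHDF3-ADAR cells the differences were 0.135 and 0.136, with the same limit and closer counts (4283 and 4664). In YTHDF2-ADAR cells they were 0.0154 and 0.0279, and binding and depth cannot be told apart there because both differences lay within the spread of random sets. The reading that edited mRNAs are those the protein binds stays open for YTHDF1 and YTHDF3, but listed genes were also higher in the YTHDF2 and YTHDF3 RIP of YTHDF1-ADAR cells (by 0.43 and 0.44), in the YTHDF1 and YTHDF3 RIP of YTHDF2-ADAR cells (0.155 and 0.124) and in the YTHDF1 and YTHDF2 RIP of YTHDF3-ADAR cells (0.139 and 0.0641), so the difference is not particular to one antibody.

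Other splits of the same libraries were counted for each comparison, using only the libraries compared, so the real counts differ from those over all 36. In the following comparisons 1 split of 40, the real one, reached the real count, which argues against chance only as far as 40 splits can. The counts for the real split and the highest other were 24026 and 11479 for YTHDF1 RIP against input, 12498 and 2 for YTHDF2 RIP, and 14900 and 5677 for YTHDF3 RIP. They were 23362 and 6298 for YTHDF1 against YTHDF2 RIP, 23559 and 4 for YTHDF1 against YTHDF3 RIP, and 11389 and 0 for YTHDF2 against YTHDF3 RIP. For the difference between lines for YTHDF1 they were 20358 and 17070, so shuffled labels also gave many calls there. Other splits can keep part of the real grouping, so the high counts of some of them do not show a structure beyond the groups. The source of these high counts was not traced. For the differences between lines, YTHDF2 gave 0 genes in the real split and 97 in the highest other, and YTHDF3 0 and 0; every split (40 of 40) reaches a count of 0, so these counts decide nothing about chance. Inputs have too few splits (1 of 10 reached the real count): 1620 and 0 for YTHDF1-ADAR against YTHDF2-ADAR, 1719 and 0 against YTHDF3-ADAR, and 3188 and 4 for YTHDF2-ADAR against YTHDF3-ADAR.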

How the results depend on the processing

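The settings that leave out the 6 YTHDF1 RIP libraries, or the input and YTHDF2 RIP libraries next to them on the first principal component (below, the 2 neighbouring libraries), and the setting with protein-coding genes only, were chosen after the data were seen. Apart from leaving out libraries, 2894 of the values of named genes kept their side of the limit, 86 came to pass it, 177 ceased to pass it and 81 reversed. With each library left out these numbers were 8799, 182, 232 and 3. A change of sign was counted as reversed only where the main value or the value under the setting passed the limit. Changes of sign among uncalled values are thus counted as kept, and interactions were judged by adjusted p alone. Where a setting tests fewer genes, its own make-up can lower the count. Leaving out libraries lowered some counts and raised others (1088 genes for YTHDF2-ADAR against YTHDF3-ADAR inputs, but 1480 with the 9 inputs only), and the cause was not tested. With 3 libraries per group, a 1.5-fold change was often missed on simulated data of YTHDF2 RIP against input (30 of 67 genes called, of 28404 genes simulated), and the interactions of YTHDF2 and YTHDF3 RIP called 0 of 67, and 28826 genes had too few counts to be tested at these depths.

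Leaving out each library in turn gave 23925 to 25476 genes for YTHDF1 RIP against input, 11843 to 13351 for YTHDF2 RIP, 14638 to 16031 for YTHDF3 RIP, 23695 to 25025 for YTHDF1 against YTHDF2 RIP, 23351 to 24504 for YTHDF1 against YTHDF3 RIP and 10697 to 12008 for YTHDF2 against YTHDF3 RIP. For inputs the ranges were 1093 (without YTHDF1-ADAR input replicate 1) to 8448 (without its replicate 3) for YTHDF1-ADAR against YTHDF2-ADAR, 1095 and 7141 against YTHDF3-ADAR without the same libraries, and 586 to 1231 for YTHDF2-ADAR against YTHDF3-ADAR. Without YTHDF2-ADAR input replicate 1 or 2 the first was 2999 or 3243, without YTHDF3-ADAR input replicate 1 or 2 the second was 2791 or 2800, and without replicates 1, 2 and 3 of YTHDF2-ADAR and of YTHDF3-ADAR input the third was 622, 618, 591, 610, 586 and 677. Differences between lines ranged from 16949 to 21011 for YTHDF1, 0 to 1 for YTHDF2 and 0 to 4 for YTHDF3.

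Equal replicate numbers did not pair libraries across all groups, so libraries were treated as not paired. Of 54 pairs of libraries within a line with the same number, 9 had a residual correlation over 0.1, with a median of 0.00322 against -0.00512 for different numbers. Between YTHDF2 and YTHDF3 RIP, all 3 pairs in YTHDF1-ADAR cells (0.233, 0.138 and 0.418) and 2 of 3 in YTHDF2-ADAR cells (0.229 and 0.131) were over 0.1, but not every library correlated best with its own number (in YTHDF1-ADAR cells 0.236 for replicates 2 and 1), so shared preparations there stay open. A block for replicate number left 0 genes for the difference between lines in YTHDF3 RIP. For editing, a minimum coverage, Fisher's test, a replicate left out and a replicate block were not run, because the editing values used here are pooled over replicates; no paired analysis was possible for editing because of this pooling.

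Differences in enrichment between lines moved with the method. For YTHDF2 RIP, where edgeR's quasi-likelihood test called 0 genes (1064 at an unadjusted p under 0.05), DESeq2 called 3 and edgeR without a filter 112. For YTHDF3 RIP, with 2 genes, DESeq2 called 6, its size factors 1, total counts 1, no filter 238, a mean of at least 100 counts 1, coding genes only 1 and the model without the 6 YTHDF1 RIP libraries 0. For YTHDF1 RIP the count was 9744 with at least 100 counts, 10136 with coding genes only and 16949 without YTHDF1-ADAR input replicate 1.

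Counts of called genes were lower in several settings. At a mean of at least 100 counts there were 12401 for YTHDF1 RIP, 11432 for YTHDF1 against YTHDF2 RIP, 11454 for YTHDF1 against YTHDF3 RIP, and 1931 and 2025 for YTHDF1-ADAR input against the others. With coding genes only these were 12647, 11850, 11862, 2229 and 2452. With glmTreat at 1.5-fold YTHDF2 RIP had 2932, YTHDF3 RIP 5536, YTHDF1 against YTHDF2 RIP 15652, YTHDF1 against YTHDF3 RIP 15091 and YTHDF2 against YTHDF3 RIP 2072. Scaling to mitochondrial mRNAs gave 5118 for YTHDF2 RIP and 3856 for YTHDF2 against YTHDF3 RIP. In YTHDF1-ADAR cells alone the counts were 15755, 7678 and 10049 for the RIPs against input and 12447, 13087 and 6114 for YTHDF1 against YTHDF2, YTHDF1 against YTHDF3 and YTHDF2 against YTHDF3 RIP. In YTHDF2-ADAR cells YTHDF2 RIP had 6466 and YTHDF2 against YTHDF3 RIP 6505; in YTHDF3-ADAR cells YTHDF2 RIP had 6022, YTHDF3 RIP 9441 and YTHDF2 against YTHDF3 RIP 4700. Without the 6 YTHDF1 RIP libraries YTHDF1 RIP had 15063, YTHDF1 against YTHDF2 RIP 12230 and YTHDF1 against YTHDF3 RIP 12794. Without the 2 neighbouring libraries YTHDF1-ADAR inputs differed in 1528 and 1555 genes from the others.

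Splits moved with scaling, count limits, test limits and libraries. The split of higher and lower genes for YTHDF1-ADAR against YTHDF2-ADAR inputs was 5182 and 621 by total counts, 4174 and 2318 by DESeq2, 4094 and 2244 without a filter, 2312 and 1467 with the 9 inputs only, 1144 and 787 at 100 counts, 1395 and 834 with coding genes, and 987 and 541 without the 2 neighbouring libraries. Against YTHDF3-ADAR inputs it was 1853 and 1678 with 9 inputs, 1108 and 917 at 100 counts and 720 and 835 without the 2 neighbouring libraries, and for YTHDF2-ADAR against YTHDF3-ADAR 296 and 874 by total counts and 552 and 571 without a filter. At 100 counts YTHDF2 RIP split 5678 and 4474, YTHDF3 RIP 6590 and 4948, YTHDF1 against YTHDF2 RIP 5613 and 5819 and YTHDF1 against YTHDF3 RIP 5782 and 5672. With glmTreat the splits were 672 and 2260 for YTHDF2 RIP, 1501 and 4035 for YTHDF3 RIP and 1461 and 611 between these RIPs. Without the 6 libraries YTHDF1 RIP split 6638 and 8425 (median -0.21), YTHDF1 against YTHDF2 RIP 5916 and 6314 and YTHDF1 against YTHDF3 RIP 5719 and 7075; with the libraries of the arms compared only, the last was 10765 and 12794.

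Single genes reversed as follows, in log2 units. By total counts YTHDF1 RIP against input gave YTHDF2 0.29, ADAR 0.0122 and METTL14 0.14. At 100 counts it gave YTHDF2 0.33, ADAR 0.0421, METTL3 0.0258 and METTL14 0.17, with SON 0.24 for YTHDF1 against YTHDF2 RIP and METTL3 0.24 for YTHDF1 against YTHDF3 RIP. With coding genes only it gave YTHDF2 0.25 and METTL14 0.0927, and METTL3 0.24 for YTHDF1 against YTHDF3 RIP. By mitochondrial mRNAs YTHDF1 RIP gave YTHDF1 -1.05, YTHDF3 -0.62, ADARB1 -0.16, SON -0.78 and CREBBP -0.43, YTHDF3 RIP METTL3 0.19, YTHDF1 against YTHDF2 RIP YTHDF3 -1.28, ADARB1 -1.02, METTL3 -1.37, METTL14 -1.26, CREBBP -1.22 and MALAT1 -0.18, and YTHDF1 against YTHDF3 RIP ADARB1 -1.40 and RPL30 -1.53.

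In YTHDF1-ADAR cells alone YTHDF1 RIP gave YTHDF2 1.11, ADAR 1.01 and MYC 1.12, YTHDF1 against YTHDF2 RIP YTHDF1 1.497, YTHDF2 0.25, ADAR 0.39, METTL3 -0.43, SON 1.11, ACTB 0.54 and MYC 0.82, and YTHDF1 against YTHDF3 RIP YTHDF1 1.37, YTHDF2 0.90, YTHDF3 1.31, SON 0.70, CREBBP 0.81, ACTB 0.91, MYC 0.94 and GAPDH 0.34. In YTHDF2-ADAR cells alone YTHDF1 RIP gave YTHDF1 -0.98, YTHDF3 -0.16, METTL3 0.13 and SON -0.25, YTHDF1 against YTHDF2 RIP YTHDF3 -0.49 and YTHDF1 against YTHDF3 RIP METTL3 0.40. In YTHDF3-ADAR cells alone YTHDF1 RIP gave YTHDF1 -1.04, YTHDF3 -0.31, ADARB1 -1.06 and SON -0.36, YTHDF1 against YTHDF2 RIP YTHDF3 -0.84 and ADARB1 -1.72, and YTHDF1 against YTHDF3 RIP ADARB1 -1.89 and METTL3 0.32. Without the 6 libraries YTHDF1 RIP gave YTHDF2 1.14, ADAR 1.04, METTL14 0.0108 and MYC 1.14, YTHDF1 against YTHDF2 RIP YTHDF1 1.44, YTHDF2 0.17, ADAR 0.32, METTL3 -0.50, SON 1.05, ACTB 0.49, MYC 0.76 and MALAT1 -0.0049, and YTHDF1 against YTHDF3 RIP YTHDF1 1.21, YTHDF2 0.74, YTHDF3 1.15, SON 0.54, CREBBP 0.66, ACTB 0.76, MYC 0.78 and GAPDH 0.18. Without the 6 libraries, YTHDF1 RIP was read in YTHDF1-ADAR cells alone. In the full model METTL14 was at -0.0159 in those cells for YTHDF1 RIP against input. MALAT1 was at 0.0519 there for YTHDF1 against YTHDF2 RIP, so the signs of METTL14 and MALAT1 turned with the refit. The cause of the reversals was not tested. For YTHDF1 against YTHDF2 RIP METTL3 was -0.24 without the 2 neighbouring libraries and without YTHDF1-ADAR YTHDF1 RIP replicate 3 or YTHDF2 RIP replicate 3, and with each library left out in turn it lay between -0.24 and 0.0586. For YTHDF1 against YTHDF3 RIP ADARB1 was -0.0055 without YTHDF3-ADAR YTHDF1 RIP replicate 2, and with the libraries of these arms only ADARB1 was -0.12 and RPL30 -0.25.

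Gene list calls numbered 130, of which 1 held with a correlation estimated per list; fry called 135, with 33 list results gained and 29 lost, held 1 of 15, 6 of 16 and 2 of 5 calls between inputs (YTHDF1-ADAR against YTHDF2-ADAR, YTHDF1-ADAR against YTHDF3-ADAR, YTHDF2-ADAR against YTHDF3-ADAR), and reversed interferon-stimulated genes for YTHDF1 against YTHDF3 RIP (adjusted p = 0.0495). Genes higher in all 3 RIPs (69 at 2-fold) numbered 1752 with no minimum fold, 360 at 1.5-fold, 21 and 27 with the inputs handed out in a second and a further way, and 33 with YTHDF1 RIP of YTHDF1-ADAR cells only; lower genes (1334 at 2-fold) numbered 3927 with no minimum and 2482 at 1.5-fold. The percent of genes with editing above input, for YTHDF1, YTHDF2 and YTHDF3 RIP, was 91.1, 87.3 and 83.1 in YTHDF1-ADAR cells among genes at 10 percent or more in the RIP, 69.3, 53.9 and 65.1 in YTHDF2-ADAR cells and 68.5, 57.0 and 69.8 in YTHDF3-ADAR cells. Choosing genes by a high level in the RIP favours the RIP by construction, so these values say nothing about stability. Weighted by sites it was 95.5, 94.4 and 91.3 in YTHDF1-ADAR cells, 31.1 for YTHDF1 RIP of YTHDF2-ADAR cells, and 25.1, 57.1 and 65.9 in YTHDF3-ADAR cells, from the authors' deposited tables.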

Other observations

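Genes outside the report's comparisons of groups added to the picture of editing. In the authors' deposited table, 22 genes were called as edited more in YTHDF1 RIP than in input in both YTHDF2-ADAR and YTHDF3-ADAR cells. These are the 6 YTHDF1 RIP libraries that stand apart, and in the authors' deposited table more genes there lay below input (1307 and 1791) than above it (698 and 768). They included the RNA-binding and splicing genes SFPQ, SRSF7, SF1, NCL and CPEB1, the chromatin genes HDAC1 and KMT2C, and AMOT, a gene of the Hippo pathway. USP5, a deubiquitinase gene, stood at 20.3 percent in input and 93.3 in YTHDF1 RIP of YTHDF2-ADAR cells in the authors' deposited table, and at 25.1 and 91.5 in YTHDF3-ADAR cells. AMOT stood at 27.7 and 92.3 in YTHDF2-ADAR cells in the same authors' deposited table, and DDX3X, a helicase gene, at 37.0 and 97.0 in YTHDF3-ADAR cells. Each of these values for USP5, AMOT and DDX3X rests on 1 site in the authors' deposited table. ADARB1 had 11 sites in YTHDF2-ADAR cells and fell from 17.1 to 7.46 percent in the authors' deposited table.

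The authors' deposited DESeq2 table was compared with the fold changes computed here; its reference group and libraries are not given in the sources used here. Across 31786 genes, which are not independent replicates, the authors' deposited fold changes had correlations of 0.981, 0.953 and 0.966 with the averages over lines for YTHDF1, YTHDF2 and YTHDF3 RIP. For YTHDF1 RIP by line they were 0.341 in YTHDF1-ADAR, 0.916 in YTHDF2-ADAR and 0.925 in YTHDF3-ADAR cells.

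MIR3648 took 5.63 percent of counts in input replicate 1 of YTHDF1-ADAR cells and 0.0328 to 0.304 in the other 8 inputs. It took 4.03 percent in YTHDF2 RIP replicate 3 of these cells and 3.13 to 7.52 in the 6 libraries that stand apart.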
